A study of Ectocarpus sp. Ec460 and Ectocarpus sp. Ec457 with 44 samples.

How the data were processed

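Samples were grouped by the sex and the antibody or assay named in the labels. The series comprised 44 samples: 4 RNA-seq libraries, 24 ChIP-seq samples of 6 histone marks and 16 control samples (8 input, 8 histone H3). The cultures of each sex were duplicates per the labels' protocols, with all female samples labelled Ec460 and all male samples Ec457, and all were mature gametophytes 4 weeks old, grown at 13 °C with 12 h of light at 20 µmol of photons per square metre and second. Chromatin had been fixed with 1% formaldehyde, and RNA libraries were made with a strand-specific kit after DNase treatment, per the labels' protocols.

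The deposited count table gave raw read counts per gene and library, made by the authors with featureCounts 1.6.3 over whole gene spans of the annotation EctsiV2, per the file headers. The recorded command carried no strand option and no read-pair option. Strand was thus not used to tell apart reads of a gene and of an overlapping or antisense gene. Whether reads in such overlaps were dropped or counted was not examined here. Intronic reads were counted. TopHat2 and Bowtie2 were among the tools in the submitters' processing notes. A second deposited table held the authors' own DESeq2 comparison of males with females, with log2 fold changes with standard errors, a Wald score, and p-values and adjusted p-values per gene, per the file headers. Only counts of calls were taken from it. The peak lists were made with MACS2 for H3K4me3, H3K9ac and H3K27ac and with SICER for H3K36me3, H4K20me3 and H3K79me2, per the file headers and names as well as the labels, and the submitters' processing notes give MACS2 2.1.1 and SICER 1.1. The H3K79me2 lists are named SICER2, unlike those of H3K36me3 and H4K20me3, so the caller may differ between them. Each list belongs to both samples of its sex and mark per the labels, so peaks are not resolved by replicate. The score of each peak is the authors' deposited value. Its meaning is not stated in the sources used here, and it served only to rank peaks within a list. The genome build of the peak lists is not given in the sources used here. Their sequence names are those of the gene table, and gene and peak coordinates were used together on that basis. No ChIP read depths, input or H3 values were analysed here.

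Coordinates are 1-based. SICER intervals ended on the last base of a window and were extended by 1 bp so that both kinds of list had the same convention. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with sex as the group (15365 of 18462 genes), libraries were scaled by TMM, and sex was tested with glmQLFit and glmQLFTest with Benjamini-Hochberg adjustment at 0.05. The log2 fold is female minus male, and its standard error is the absolute log2 fold divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. The biological coefficient of variation was 0.176. With total counts of 43119243 to 51431481 per library, 3 counts correspond to between 0.0583 and 0.0696 CPM of unscaled library size. Correlations of log2 CPM were 0.986 between the replicates of each sex and 0.960 to 0.970 between the sexes. Each sex had 2 cultures, so p-values rest on the spread between them.

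Sex-limited genes had at least 10 counts in both libraries of a sex and at most 1 in each library of the other. Chromosome 13, the sex chromosome, was compared with the other 27 numbered chromosomes by a two-sided Fisher exact test on called genes, and its direction by camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation. Genes of chr_00 were left out of that test, since their place is unknown. Gene lists by product description had been planned, but the files used here hold no descriptions, so these lists were not built. The rule for named genes took the 10 genes of largest absolute log2 fold in each direction on autosomes and chromosome 13 (adjusted p below 0.05, no overlap between the libraries of the sexes, mean of at least 1 CPM, sex-limited genes left out), the 5 sex-limited genes of highest expression per sex, and 4 fixed loci, plus the widest peak of each list. Because the IDs come without names, no more than 2 genes per direction are printed for each part of the rule, and the rest are summarised.

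Peak lists were compared with bedtools 2.31.1: the share of peaks meeting a peak of the other sex by at least 1 bp, and the Jaccard index, beside 20 random shifts along the chromosomes. Chromosome length was the span of the peaks of all 12 lists, as no reference length was used. A gene counted as marked when a MACS2 peak lay within 500 bp of its annotated start or when SICER peaks covered at least 50% of its length. Shares carry 95% Wilson intervals for counting error, computed with scipy 1.17.1. Genes marked in a single sex were tested for bias by a two-sided Fisher exact test with adjustment over 6 marks, and odds ratios were formed with 0.5 added to each cell.

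The tests, the rule for named genes and 51 alternatives were fixed before the data were examined, and 5 alternatives were added afterwards. The alternatives cover other scalings (RLE, upper quartile), filters, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, other thresholds, other gene windows, stricter overlap, merged peaks and the upper part of each list by score. The procedure was tested on simulated counts for the female against male comparison, with 200 of 15365 genes changed. With edgeR, 46% of 50 genes with a log2 fold of 1, 98% of 50 with a log2 fold of 2 and 100% of 50 with a log2 fold of 3 were recovered, and 8.51% of the 188 calls were false. Simulated peak lists with 700 shared peaks gave back 700.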

Results

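Histone marks and gene expression were compared between mature male and female gametophytes of Ectocarpus, a small filamentous brown alga in which sex is expressed in the haploid generation and is set by a U chromosome in females and a V chromosome in males. All female samples were labelled as strain Ec460 and all male samples as strain Ec457, so that differences between the sexes cannot be separated from differences between these strains. The whole organisms were 4 weeks old and had been grown at 13 °C under 12 h of light. The samples comprised 4 RNA-seq libraries (2 cultures per sex), 24 ChIP-seq samples for 6 histone marks (2 per mark and sex), and 16 input and histone H3 control samples. The controls came in 2 labelled sets, the second listed together with the H3K79me2 samples. Differences between H3K79me2 and the other marks therefore cannot be separated from a difference between sets. The RNA came from the same duplicate cultures as the chromatin, per the labels' protocols. Total gene counts were 48504500 and 51431481 in the female RNA libraries and 43119243 and 47540382 in the male libraries. The ChIP-seq data analysed here were 12 peak lists, 1 for each mark in each sex, so that differences between lists had no replicate check and were given without a p-value across replicates. The gene table held 18462 genes on chromosomes numbered 1 to 28, on unplaced sequence called chr_00, and on a separate female-specific sequence called sdr_f, referred to here as the U sequence. The files paired the gene IDs with no names or product descriptions.

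The first comparison asked which genes differed in expression between the sexes. Of 15365 genes tested, 137 were higher in females and 68 were higher in males (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Most of these differences were large, since 133 and 63 of them also had an absolute log2 fold of at least 1. All 17 tested genes of the U sequence were higher in females, and 20 of the 23 tested genes in a male-limited interval of chromosome 13 were higher in males. The U sequence is female-specific and the interval was delimited on these libraries, so both numbers follow largely from the regions themselves. On the autosomes, 98 genes were higher in females and 40 in males, which was 0.972% of 14201 tested genes. The unplaced sequence held 18 genes higher in females and 6 higher in males among 783 tested. Chromosome 6 held 14 genes higher in females and 0 higher in males.

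For the largest changes, sex-limited genes, genes of chr_00 and genes below a mean of 1 CPM were left out. Outside the sex-specific sequences, the 10 largest female-higher changes then ranged from 4.32 to 7.38 on the log2 scale, and all 10 genes were autosomal. Ec-15_002310 (chromosome 15, 2530750 to 2530938) had a mean of 4.09 ± 0.72 CPM (SD, n = 2) in females and 0.021 ± 0.030 CPM (SD, n = 2) in males, a log2 fold of 7.38 (SE 0.59, edgeR adjusted p = 8.4e-04). The size of this fold is uncertain, since the male libraries had 0 and 2 counts: the ratio of summed counts was 186 (95% counting interval 51.2 to 1541), and the log2 fold was 6.52 without male replicate 1 and 10.61 without male replicate 2. Ec-18_001930 (chromosome 18, 1892022 to 1900473) had 21.6 ± 3.2 CPM in females and 0.247 ± 0.185 CPM in males, a log2 fold of 6.41 (SE 0.41, edgeR adjusted p = 2.5e-04), which was 5.83 without male replicate 1 and 7.50 without male replicate 2. Under the same limits, the 10 largest male-higher changes all lay in the male-limited interval, with log2 folds from -10.08 to -6.35. Outside that interval, the sex-limited genes Ec-13_003120 (log2 fold -8.00) and Ec-02_001965 (log2 fold -7.52) were left out by these limits. Among the remaining genes there, a list chosen after its values were seen, the 10 largest male-higher changes ranged from -6.35 to -2.06. Its first gene, Ec-23_003330 (chromosome 23, 3593958 to 3598160), had 10.0 ± 1.4 CPM in males and 0.119 ± 0.081 CPM in females, a log2 fold of -6.35 (SE 0.41, edgeR adjusted p = 2.5e-04), which was -5.81 without female replicate 1 and -7.29 without female replicate 2. Ec-21_002120 (chromosome 21, 3175835 to 3181745) had 2.89 ± 0.11 CPM in males and 0.239 ± 0.049 CPM in females, a log2 fold of -3.57 (SE 0.35, edgeR adjusted p = 0.0020).

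The number of called genes was sensitive to the model and to single libraries. DESeq2 called 282 genes higher in females and 151 higher in males, and the authors' deposited table, made with the same tool, listed 280 and 151. That table shared 202 of the 205 edgeR calls. The counts were 293 and 136 without female replicate 2, 258 and 162 without male replicate 1, and 235 and 151 without male replicate 2. A test against a fold of 1.5 left 79 and 37 genes. In every one of these settings more genes were higher in females than in males.

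**Figure D1:**
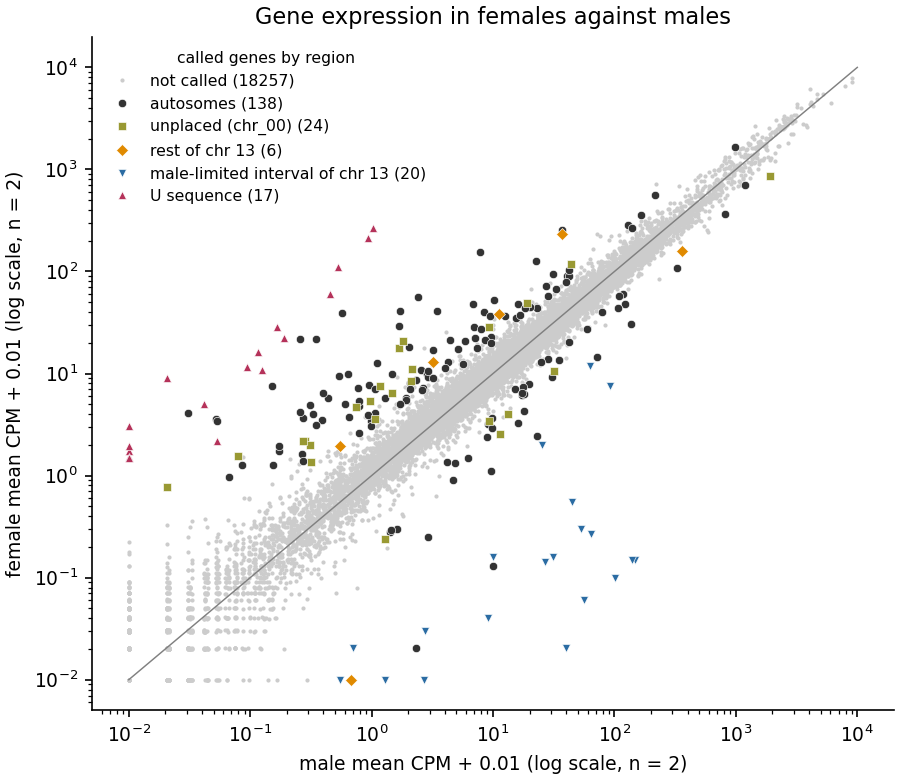
Mean CPM per gene in males (x axis) and females (y axis), each plus 0.01 on log scales, with n = 2 libraries per sex; the line marks equal expression. Coloured symbols are the called genes by region: the 17 U-sequence genes lie above the line, the 20 genes of the male-limited interval lie below it, and the 138 autosomal genes lie on both sides.

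Genes whose transcripts were restricted to a single sex were then listed by count. At least 10 counts in both libraries of a sex and at most 1 count in each library of the other were found for 9 genes in females and 9 in males. These numbers depended on the limits, with 5 and 4 genes at a minimum of 20 counts and 0 in the other sex, 16 and 11 at a minimum of 5 and at most 1, and 18 and 12 at a minimum of 10 and at most 3. The female genes comprised 6 of the U sequence and 3 elsewhere, and the male genes comprised 7 in the male-limited interval, 1 elsewhere on chromosome 13 and 1 on chromosome 2. Some members met the count rule but were not called by edgeR. These were Ec-06_005340 and Ec-09_003810 in females (edgeR adjusted p = 0.069 and 0.097) and Ec-13_001870 in males (edgeR adjusted p = 0.066). The gene with the highest male expression in this class was Ec-13_001750 (chromosome 13, 2861184 to 2913866), the locus of an HMG-domain protein that the literature on brown algae holds to be the leading candidate male-determining factor. This identity does not come from the files. The gene overlaps another annotated gene, and strand was not used to tell their reads apart. It had 1760 and 1816 counts in the male libraries and 1 and 0 in the female libraries, a ratio of 3942 (95% counting interval 707 to 155740). The female gene with the highest expression in this class, Ec-sdr_f_000110 (U sequence, 410921 to 462753), had 449 and 458 counts in females and 0 and 1 in males, a ratio of 823 (95% counting interval 147 to 32535). Ec-sdr_f_000070, with 164 and 140 female counts and no male count, was at least 91.9-fold higher in females, against a floor of 3 counts over both male libraries. Ec-13_002030, with 96 and 152 male counts and no female count, was at least 91.1-fold higher in males on the same floor. As the class was chosen on these libraries, its membership is no independent evidence, and intervals and floors cover counting error only.

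The male-limited interval spanned positions 2775867 to 3669521 of chromosome 13 (894 kb, 30 annotated genes) and was delimited after the data were seen, from genes with male counts and a female mean below 5% of the male mean. Its genes had a median of 17.7 CPM in males and 0.0401 CPM in females. The 22 genes of the U sequence had a median of 4.03 CPM in females and 0.0368 CPM in males. The interval was not silent in females throughout, as 5 of its genes reached at least 1 CPM there. Of these, Ec-13_001800 and Ec-13_001810, named after their values were seen, had 78.3 and 496 CPM in females and 127 and 723 CPM in males and were not called. With the sex-limited genes left out, the largest changes in the interval included those of Ec-13_001910 (chromosome 13, 3155088 to 3242491), at 100.4 ± 8.8 CPM in males and 0.089 ± 0.096 CPM in females (n = 2 each), and of Ec-13_001710 (chromosome 13, 2775867 to 2800680), at 56.0 ± 8.2 and 0.050 ± 0.016 CPM. Their log2 folds were -10.08 (SE 0.42) and -10.05 (SE 0.33), with edgeR adjusted p-values of 2.0e-05 and 4.3e-06. That of Ec-13_001910, with 1 and 8 female counts, was -9.30 without female replicate 1 and -12.08 without female replicate 2, so the order of these genes is not settled.

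Whether the rest of the sex chromosome, which pairs and recombines, was also enriched in sex-biased genes was asked next. With the sex-limited genes and the U sequence left out, 19 of 356 tested genes of chromosome 13 (5.34%) and 137 of 14198 autosomal genes (0.965%) were called. The odds ratio was 5.78 (95% interval 3.34 to 9.52, two-sided Fisher exact p = 8.6e-09). As a set, the chromosome 13 genes had female-minus-male differences shifted toward males relative to those of the autosomal genes. The camera p was 0.0176 with the preset correlation and 0.0375 with an estimated correlation. Both calls rested on the male-limited interval: without it, an alternative chosen after seeing the data, 5 of 340 genes (1.47%) were called, with an odds ratio of 1.53 (95% interval 0.49 to 3.70, two-sided Fisher exact p = 0.39), and the camera p was 0.395. In the rest of chromosome 13, 4 genes were higher in females and 2 in males. The 4 female-higher genes, named after their values were seen, were Ec-13_003240 (from 5013797), Ec-13_003250, Ec-13_003430 and Ec-13_003720 (up to 5454274). All but Ec-13_003430 carried H3K27ac at their start in the female list and not in the male list, and H3K9ac there in both sexes.

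**Figure D2:**
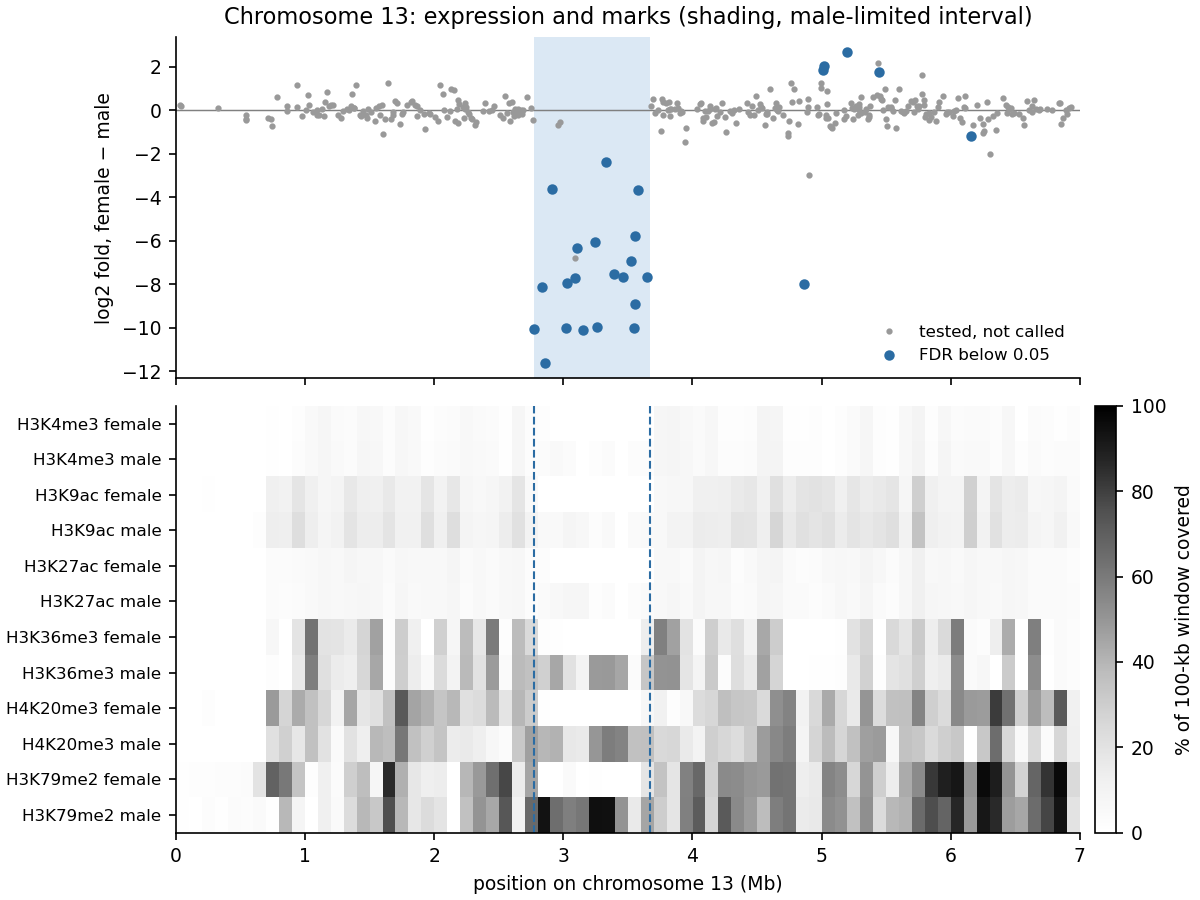
Upper panel: log2 fold (female minus male) of each tested gene against its start on chromosome 13 in Mb, with called genes in blue and the male-limited interval shaded. Lower panel: percent of each 100-kb window covered by each of the 12 peak lists, with dashed lines at the interval's ends; inside it the male H3K79me2 list covered 65.3% of bases and the female list 0.537%.

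Of the loci fixed before the data were examined, those of the life-cycle regulators were expressed in both sexes and none was called. Ec-14_005920, the locus of the TALE homeodomain factor OUROBOROS, which is needed for the switch from gametophyte to sporophyte, had 15.5 ± 1.6 CPM in females and 16.3 ± 1.8 CPM in males (n = 2 each, log2 fold -0.07, SE 0.20, edgeR adjusted p = 0.93). Ec-27_006660, the locus of its partner SAMSARA, had 4.07 ± 0.27 CPM in females and 1.96 ± 0.83 CPM in males (log2 fold 1.05, SE 0.33, edgeR adjusted p = 0.25). Without male replicate 2 its log2 fold was 1.56 with an edgeR adjusted p of 0.032, and across the other alternatives the adjusted p ranged from 0.15 to 0.65. Ec-27_002610, the locus of IMMEDIATE UPRIGHT, a regulator of early filament development, had 3.06 ± 0.07 CPM in females and 2.92 ± 0.21 CPM in males (log2 fold 0.07, SE 0.24, edgeR adjusted p = 0.95). These names come from the literature, not from the files. All samples carried the phenotype label imm, whose meaning is not given in the sources used here, and whether it refers to this locus or to the genotype of the cultures was left open.

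The chromatin data covered marks of active gene starts (H3K4me3, H3K9ac and H3K27ac), H3K36me3, which in many eukaryotes follows transcribed gene bodies, and H4K20me3 and H3K79me2. The female and male lists were close in size for the first group of marks. H3K4me3 had 10041 female and 10021 male peaks over 15.6 and 16.4 Mb, H3K9ac had 16788 and 17202 peaks over 21.1 and 23.8 Mb, and H3K27ac had 13351 and 13035 peaks over 15.4 and 15.1 Mb. Median widths of these peaks lay between 1172 and 1614 bp. The other marks formed broader domains. H3K36me3 had 11813 female and 12706 male peaks over 59.9 and 61.9 Mb, H4K20me3 had 4418 and 5291 peaks over 26.6 and 22.8 Mb, and H3K79me2 had 4611 and 5502 peaks over 51.9 and 52.2 Mb, with median widths of 2800 to 7600 bp. The widest peak of any list was a female H3K79me2 domain of 245.8 kb on chromosome 21 (911601 to 1157400). The widest H3K36me3 peaks of the sexes shared their place on chromosome 24, at 44801 to 117600 in females and 44601 to 166400 in males. The widest H4K20me3 peaks lay on chromosome 6 in females (4352401 to 4441600) and on chromosome 13 in males (6330401 to 6379400), and the widest male H3K79me2 peak lay on chromosome 6 (4319601 to 4459600). Widest peaks of the remaining lists were 5.90 kb (female H3K4me3, chromosome 12, 1934082 to 1939981), 6.06 kb (male H3K4me3, chromosome 21, 6101479 to 6107534), 10.8 and 10.9 kb (H3K9ac, chromosome 5, from 3673574 in both sexes), and 4.95 and 4.86 kb (H3K27ac, chromosome 18, from 2298588 in females and 2298652 in males).

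Female and male peaks coincided for all marks except H4K20me3. Overlap of at least 1 bp with the other sex was found for 97.2% of female and 93.7% of male H3K4me3 peaks, 95.7% and 86.4% of H3K9ac peaks, 90.4% and 92.9% of H3K27ac peaks, 89.3% and 82.7% of H3K36me3 peaks, and 82.6% and 81.1% of H3K79me2 peaks. For H4K20me3 these shares were 32.3% (95% Wilson interval 30.9 to 33.6) and 26.4% (25.2 to 27.6). The Jaccard index of covered bases was 0.889 for H3K4me3, 0.834 for H3K9ac, 0.842 for H3K27ac, 0.726 for H3K36me3 and 0.783 for H3K79me2, against 0.203 for H4K20me3. Random shifts of the lists along the chromosomes gave a mean index of 0.0811 for H4K20me3 and between 0.0476 and 0.204 for the other marks. The H4K20me3 lists also kept different company within each sex. In females 65.2% of H4K20me3 peaks met an H3K9ac peak and 35.2% met an H3K36me3 peak, whereas in males 30.9% met H3K9ac and 60% met H3K36me3.

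The sex chromosome was covered less by H3K4me3, H3K27ac and H3K36me3 and more by H3K79me2 and H4K20me3 than the autosomes in both sexes. Coverage was per base and was not adjusted for gene density or expression. The start of chromosome 13, up to position 600000, was nearly empty in all 12 lists, with at most 3.2% of any 100-kb window covered. It was counted in the length, which lowers every share given for this chromosome, and why it was empty was not tested. Genes of chromosome 13 outside the male-limited interval had a median of 4.92 CPM in females and 4.41 CPM in males, against 10.7 and 10.3 CPM on the autosomes. H3K4me3 covered 2.93% of chromosome 13 in females and 3.51% in males, the lowest of 28 chromosomes in each list, against autosomal medians of 8.60% and 8.98%. H3K27ac (4.37% and 4.72%, medians 8.56% and 8.37%) and H3K36me3 (16.1% and 19.1%, medians 33.7% and 35.1%) were also lowest on chromosome 13. H3K79me2 covered 36.3% of chromosome 13 in females and 42.5% in males, the highest of 28 chromosomes, against autosomal ranges of 18.0 to 32.8% and 18.5 to 33.4%. H4K20me3 was likewise highest there, at 27.3% and 26.1% against medians of 14.8% and 12.5%. H3K9ac was within the autosomal range, at 10.1% in females and 12.3% in males. These ranks of H3K4me3, H3K27ac, H3K36me3, H4K20me3 and H3K79me2 held when the male-limited interval was left out, an alternative chosen after seeing the data, with 3.34% and 3.72% of the remainder covered by H3K4me3 and 41.6% and 39.1% by H3K79me2.

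**Figure D3:**
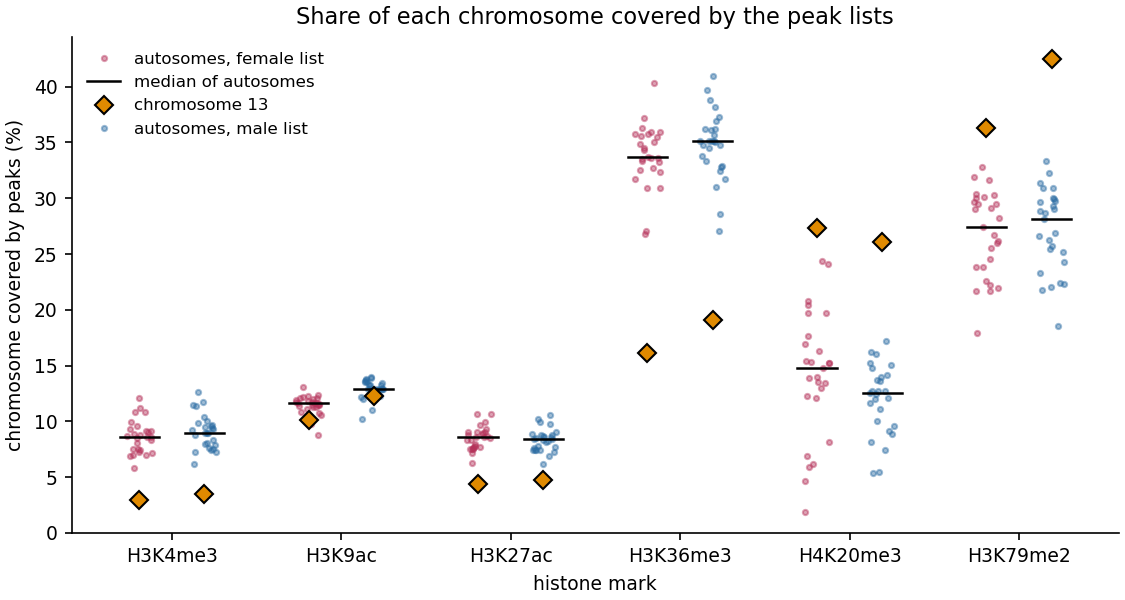
Percent of each chromosome covered by peaks (y axis) for the 6 marks (x axis), female lists in red and male lists in blue; points are the 27 autosomes, black bars their median and orange diamonds chromosome 13. Chromosome 13 lies below all autosomes for H3K4me3, H3K27ac and H3K36me3 and above all of them for H4K20me3 and H3K79me2.

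The U sequence was marked mainly in females and the male-limited interval mainly in males. Whether females lack the whole interval was not tested, as it was delimited from RNA counts. In males, H3K79me2 covered 65.3% of the male-limited interval, H4K20me3 40.9%, H3K36me3 31.7%, H3K9ac 4.08%, H3K27ac 3.54% and H3K4me3 2.09%. In females, H3K79me2 covered 42.4% of the 870-kb U sequence, H4K20me3 11.2%, H3K36me3 4.90%, H3K9ac 1.68%, H3K27ac 1.42% and H3K4me3 0.562%. Female lists covered at most 0.537% of the male-limited interval, and male lists covered at most 0.299% of the U sequence. Of the 20 male-higher genes of the interval, 9 had H3K4me3 at their start and 13 were covered by H3K79me2 over at least 50% of their length in males. Of the 17 female-higher genes of the U sequence, 3 had H3K4me3 at their start and 11 were covered by H3K79me2 in females.

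Marks were then assigned to genes and set against expression in the same sex. H3K4me3 lay within 500 bp of the start of 12183 genes in females and 12264 in males, H3K9ac of 13466 and 13652, and H3K27ac of 12938 and 12849. H3K36me3 covered at least 50% of the length of 6666 and 7167 genes, H3K79me2 of 4308 and 4424, and H4K20me3 of 2490 and 1826. Genes with H3K4me3 in females had a median of 16.0 CPM and those without it 0.907 CPM, and the male values were 15.6 and 0.715 CPM. From the lowest to the highest quartile of expression in females, the share of genes with H3K4me3 was 26.3% (95% Wilson interval 25.0 to 27.6), 71.8%, 82.6% and 83.3% (82.2 to 84.4). H3K36me3 was more graded, at 13.5%, 30.7%, 48.3% and 51.9% in females and 14.4%, 33.4%, 52.1% and 55.3% in males. H3K79me2 went the other way, from 32.6% to 14.5% of genes in females and from 32.8% to 15.1% in males. H4K20me3 fell from 21.0% (19.8 to 22.2) to 9.49% (8.68 to 10.4) in females, and its male shares lay between 9.12% and 11.3%. For H4K20me3 the direction depended on the gene window: with any overlap of the gene body counted, the top quartile exceeded the bottom by 0.721 percentage points in females and 16.2 points in males.

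**Figure D4:**
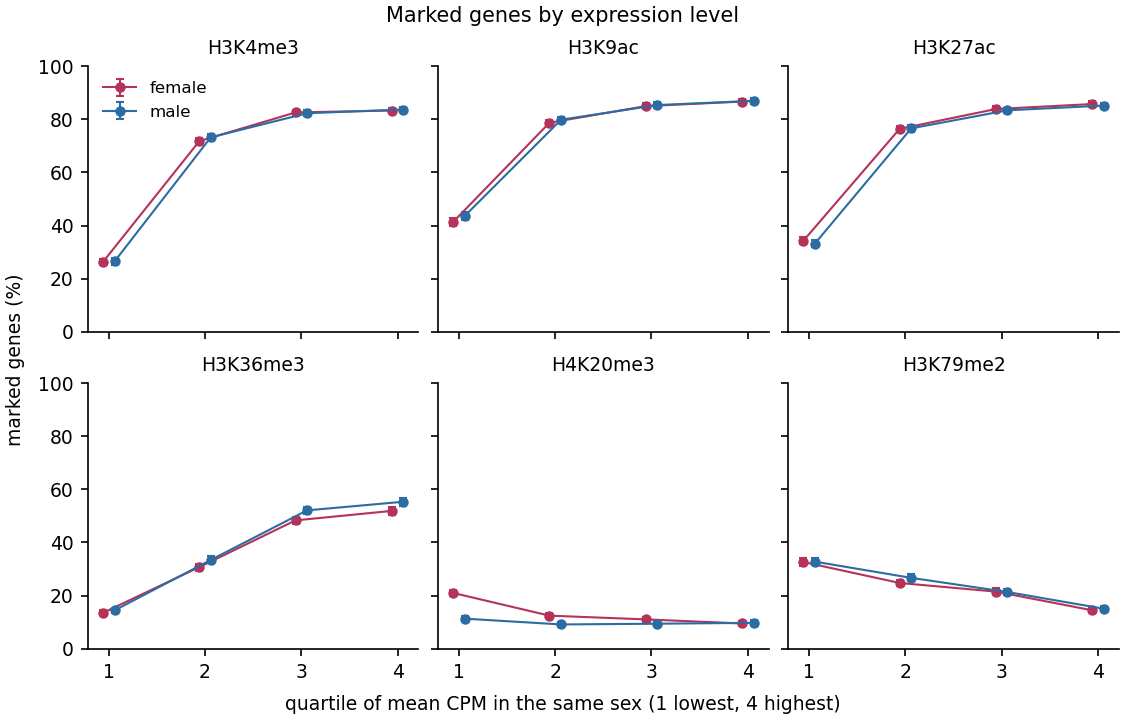
Percent of genes carrying each mark (y axis) by quartile of mean CPM in the same sex (x axis), females in red and males in blue, with 95% Wilson intervals for counting error. H3K4me3 goes from 26.3% to 83.3% in females, whereas H3K79me2 goes from 32.6% to 14.5%.

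Combinations of marks went with different levels of expression. In females, 5526 genes had H3K4me3, H3K9ac and H3K27ac at the start together with H3K36me3 over the body, with a median of 22.5 CPM, and 97.3% of them reached at least 1 CPM. The 6463 genes with the 3 start marks and no H3K36me3 had a median of 10.8 CPM. The 1382 genes with H3K79me2 and none of the other 4 of these marks had a median of 0.179 CPM, and 37.9% of them reached at least 1 CPM, while the 2263 genes with none of the 6 marks had a median of 0.736 CPM, with 48.1% at 1 CPM or more. H3K79me2 was not confined to silent genes, as the 2136 genes that carried it together with the 3 start marks had a median of 12.2 CPM. The corresponding male medians were 22.4, 9.81, 0.122, 0.497 and 11.1 CPM.

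The last comparison asked whether genes marked in a single sex were biased toward that sex. Of 85 tested genes with H3K4me3 in females only, 13 were called higher in females and 0 higher in males, and of 164 with H3K4me3 in males only, 1 was higher in females and 9 in males (two-sided Fisher exact p = 1.2e-05, Benjamini-Hochberg adjusted over 6 marks p = 7.3e-05). For H3K27ac the corresponding counts were 10 and 1 of 128 genes, and 2 and 9 of 74 genes (exact p = 0.0019, adjusted p = 0.0057). The other marks did not pass, with adjusted p = 0.0685 for H3K9ac and for H4K20me3, 0.052 for H3K79me2 and 0.28 for H3K36me3. Genes with H3K4me3 in females only had a median log2 fold of 0.24, against -0.04 for those marked in males only. On the female side, some of the 13 genes lay in a block of chromosome 6 described below, where the male list had no H3K4me3 peak. The female H3K4me3 list marked 54 of 98 autosomal female-higher genes, and 50 of 92 without that block. The male side of both associations came largely from the male-limited interval. That interval was delimited by low female expression, so male-higher calls there were largely fixed in advance and are no independent support. Without it, 13 and 0 genes remained against 1 and 2 for H3K4me3 (adjusted exact p = 0.15) and 10 and 1 against 2 and 3 for H3K27ac (adjusted exact p = 0.19). So few biased genes marked in males only leave this test little power. The 13 and 0 of 85 genes with H3K4me3 in females only were not changed by leaving the interval out. Of all 15320 genes tested there, 119 were higher in females and 46 in males. Whether the female-only genes differ from that base was not tested. The H3K4me3 association also did not pass with the higher-scoring 50% of each list (adjusted exact p = 0.52). Across the other alternatives its adjusted exact p ranged from 7.7e-08 to 4.5e-04. All of those kept the interval, so they do not show an association outside it. Most sex-biased genes did not differ in H3K4me3 between the sexes. Of 119 female-higher genes in this test, 41 had H3K4me3 in both sexes and 64 in neither, and of 60 male-higher genes these numbers were 17 and 34.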

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

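Both tests in this part, and their bounds, were chosen after the results were seen, and the first replaced earlier forms of the same test. Female peak lists held 19 peaks inside the male-limited interval of chromosome 13: 14 lay in or across the end of the gene Ec-13_001750, and the other 5 were H3K79me2 peaks elsewhere in the interval. Those 14 fell on the same few spots whatever the mark. The spot from 2876500 to 2877614 was listed in females for H3K4me3, H3K9ac, H3K27ac, H3K36me3 and H4K20me3, while the female RNA libraries had 1 and 0 counts for the gene.

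Male material as the source of the peaks at Ec-13_001750 is argued against, since it would bring in the male peaks of equal or higher score across the interval. For H3K4me3, H3K27ac, H3K36me3 and H4K20me3, 168 male peaks scored at least as high as the lowest one met at the gene, those at the gene included. Of these, 7.14% were met by a female peak of the same mark (exact 95% upper limit 12.1%), against a bound of 50%. That bound was loosened after the values were seen, so meeting it adds no support. The 12 met peaks all lay at the gene on a few shared spots, so they are not independent, as the limit assumes. The argument rests on the male peaks of these marks elsewhere in the interval, none of which was met. For the 5 H3K79me2 peaks male material stays open: 100% of them met a male H3K79me2 peak, but male peaks covered 65.3% of the interval and the exact 95% lower limit for 5 peaks was 47.8%. Reads placed on the gene from DNA elsewhere were not tested, and no biological explanation was tested.

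Male peak lists held 5 peaks on the U sequence, all between 659601 and 662200, for H3K9ac, H3K27ac and H4K20me3, outside any annotated gene. Counts on the U sequence were 30 in male replicate 1 (0.696 CPM) and 316 in male replicate 2 (6.65 CPM), against 36688 and 40118 in the female libraries. In male replicate 2 they were spread over 13 of the 22 genes and came to 0.865% of the female mean per counts sequenced, and in male replicate 1 to 0.0906% over 6 genes. Carry-over of female material and misplaced reads were not tested. Male replicate 2 also exceeded male replicate 1 at the largest female-higher changes outside the sex-specific sequences, as with 18 against 5 counts for Ec-18_001930. At some other called female-higher genes it was lower, with 23 against 25 counts for Ec-06_006290, 11 against 16 for Ec-06_006550 and 1 against 4 for Ec-06_006610. As carry-over and misplaced reads were not tested, male means and folds of strongly female-higher genes carry this doubt.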

How the results depend on the processing

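The alternatives without the male-limited interval, with chr_00 among the autosomes and with chromosome lengths from the gene table were chosen after seeing the data, and where no cause is named below, the cause was not tested. No planned gene list could be run, since no product descriptions were at hand. The 4 RNA libraries limit calls to large changes, and 1 list per sex and mark leaves chromatin differences without a replicate check. Female-higher calls exceeded male-higher calls under every alternative run. DESeq2 gave 282 and 151 genes, a fold test against 1.5 gave 79 and 37, and leaving out single libraries gave 199 to 293 and 66 to 162, with the lone library of a sex assumed to vary like the others. With the replicate number as a block, 262 genes were higher in females and 114 in males, and all 205 calls were kept. The same-numbered deviations correlated at -0.379 across the sexes, and nothing in the labels says that a number pairs cultures. Under the block the odds ratio of chromosome 13 was 4.52. Its odds ratio ranged from 3.21 to 5.81 with single libraries left out and was 1.53 without the male-limited interval, where the test no longer passed because the interval held 14 of the 19 called genes. Sex-limited genes numbered 5 and 4 with at least 20 counts and 0 in the other sex. With at least 5 counts and at most 1 there were 16 and 11, and with at least 10 and at most 3 there were 18 and 12. Of 301 alternative values for 43 named genes, 297 kept their direction and side of the threshold. The exceptions were loci not called in the report. With single libraries left out, the log2 fold ranged from -0.184 to 0.0421 for Ec-14_005920 and from -0.00553 to 0.143 for Ec-27_002610, and that of Ec-27_006660 reached 1.56 without male replicate 2, where it was called.

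Requiring at least 50% of the peak to be covered gave 93.5% of H3K4me3 peaks meeting the other sex, 87.1% of H3K9ac, 88.5% of H3K27ac, 82.8% of H3K36me3, 25.6% of H4K20me3 and 77.4% of H3K79me2. Reciprocal overlap of at least 50% gave 89.1%, 79.04%, 82.8%, 75.2%, 21.8% and 64.0% for the marks in that order, as a stricter rule must lower them. With the higher-scoring 50% of each list the shares were 90.6%, 96.5%, 93.6%, 85.0%, 35.4% and 85.4%, and with peaks within 500 bp merged 97.6%, 94.4% and 94.6% for the first 3 marks. H4K20me3 stayed lowest throughout. In the higher-scoring 50% of the lists the female share of covered length was 50.1% for H3K79me2, which turned its direction.

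Chromosome 13 over the median autosome, counted as peaks per Mb, was 1.06 in females and 1.08 in males for H3K9ac, 0.691 and 0.755 for H3K27ac, and 1.63 for male H4K20me3. With the higher-scoring 50% of each list it was 0.465 and 0.523 for H3K9ac and 0.337 and 0.363 for H3K27ac. Without the male-limited interval it was 0.999 and 1.04 for H3K9ac and 1.52 for female H3K79me2, so that the H3K9ac direction was not stable.

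Any overlap with the gene body gave 4992 genes with H4K20me3 in females and 4693 in males, and the higher-scoring 50% gave 8023 and 8038 with H3K4me3. The share of marked genes in the top minus the bottom expression quartile, in percentage points for females then males, was with any overlap 61.2 and 61.2 for H3K4me3, 49.8 and 48.1 for H3K9ac, 55.6 and 56.0 for H3K27ac, 52.0 and 53.6 for H3K36me3, 0.721 and 16.2 for H4K20me3, and -15.7 and -16.0 for H3K79me2. Within 1000 bp of the start it was 54.8 and 55.2 for H3K4me3, 41.4 and 39.8 for H3K9ac, and 48.6 and 49.3 for H3K27ac. With the higher-scoring 50% it was 49.3 and 49.1, 54.8 and 54.7, 56.6 and 56.2, 30.1 and 31.1 for H3K36me3, -9.57 for female H4K20me3, and -15.3 and -14.4 for H3K79me2. Only H4K20me3 turned its direction.

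For marks of a single sex and bias, the odds ratio (0.5 added) without the male-limited interval was 45 for H3K4me3, 9.80 for H3K27ac, 0.481 for H3K36me3 and 0.558 for H4K20me3, none passing. With the higher-scoring 50% it was 3.27 for H3K4me3, not passing. It newly passed with any overlap for H3K9ac (21), H3K36me3 (34.5), H4K20me3 (5.18) and H3K79me2 (7.67), with sex-limited genes included for H3K9ac (17.9), H4K20me3 (3.53) and H3K79me2 (11), and with DESeq2 for H3K36me3 (24.7). These settings all kept the male-limited interval.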

Other observations

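The test of genomic DNA outside the chromosome 6 block and the 3 tests on H4K20me3 were set before their values were seen. The comparison with matched genes and the test of loss of the chromosome 6 block were chosen after the pattern was seen.

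Autosomal genes with sex-biased expression carried less H3K4me3, H3K27ac and H3K36me3 than other genes of similar expression and length. Of the 98 genes higher in females, 15.3% had H3K36me3 over the gene body in females, where 10000 random lists of uncalled autosomal genes matched on mean expression and gene length had a median of 36.7% (95% of lists between 28.6 and 45.9%). H3K4me3 marked 55.1% of them, against a median of 76.5% (68.4 to 83.7%). Of the 40 genes higher in males, 5.00% had H3K36me3 in males against a median of 45% (30.0 to 57.5%), and 47.5% had H3K4me3 against 77.5% (65.0 to 90.0%). H3K27ac was also below the random range, at 64.3% of the female-higher genes (72.4 to 86.7%) and 57.5% of the male-higher genes (67.5 to 90.0%). H3K9ac was below it for the female-higher genes, at 70.4% (74.5 to 88.8%), but at the edge of it without the chromosome 6 block (75.0%, range 75.0 to 90.2%), and it was within it for the male-higher genes, at 85.0% (70.0 to 92.5%). H4K20me3 covered 27.6% of the female-higher genes in females against a median of 11.2% (6.12 to 18.4%), and 22.8% when the genes of the chromosome 6 block described next were left out. This followed the list and not the direction of the bias: the female list also covered 27.5% of the male-higher genes, and the male list covered 9.18% of the female-higher and 7.50% of the male-higher genes (random range of the latter 2.50 to 20.0%). H3K79me2 covered 35.7% of the female-higher genes, above the random range of 15.3 to 30.6%, and 32.5% of the male-higher genes, within 12.5 to 37.5%; without the chromosome 6 block the female value was 31.5%, at the upper limit of its range. These percentages describe these lists, since genes are not replicates, and no correction was made for the 12 comparisons of mark and sex.

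A block of 148 consecutive genes on chromosome 6 (4319941 to 4547478, 228 kb) was the longest run of genes that were below 1 CPM in males and covered by H3K79me2 there, and the next longest run held 32 genes. The genes were short, with a median length of 0.834 kb. Summed over the block, expression was 45.4 and 32.0 CPM in the female libraries and 2.48 and 2.67 CPM in the male libraries, and 6 of the genes were called, all higher in females. These 6 carried most of the sum, as the other 142 genes summed to 4.89 and 4.21 CPM in females and 0.836 and 0.841 CPM in males. A low male value favours calls in this direction. Outside the block, 3580 genes of the autosomes and of chromosome 13 without the male-limited interval had a male mean below 1 CPM. Their sums were 877 CPM in females and 585 CPM in males, with 29 genes called higher in females and 1 higher in males. Among the 6 called genes of the block, Ec-06_005680 (4371387 to 4373484), had 7.60 ± 1.88 CPM in females and 0.141 ± 0.068 CPM in males (n = 2 each, log2 fold 5.71, SE 0.41, edgeR adjusted p = 4.4e-04; 5.31 without male replicate 1 and 6.31 without male replicate 2), and it overlaps another annotated gene. The female lists held 14 H3K4me3 and 6 H3K36me3 peaks in the block and the male lists 0 of either, and neither sex had an H3K9ac or H3K27ac peak there. H3K79me2 covered 99.5% of the block in both sexes, and H4K20me3 covered 89.1% in females and 11.8% in males.

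Loss of this block from the male genome is argued against. Its choice rested on male H3K79me2, so that mark tests nothing, but the male H4K20me3 list, which played no part in the choice, covered 11.8% of the block, while no male list covered more than 0.299% of the U sequence. Genomic DNA in the female RNA libraries stays open. Other genes below 1 CPM in males had 0.101 of the block's female excess per kb, just above the bound of 0.1 set in advance. Genes of chr_00, the male-limited interval and the U sequence were left out of that comparison, so a value this near the bound decides little. The share of 0.101 rests on the 6 called genes, since the excess was 0.247 CPM per kb over the whole block, 0.0277 over its other 142 genes and 0.0251 outside it. A difference between the sexes, the strains or the cultures stays open too and was not tested. The product descriptions needed to say what these genes are were not used here.

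H4K20me3 was the only mark of the 6 whose female and male lists shared a minority of peaks, and weak peaks are argued against as the cause. Of the higher-scoring 50% of H4K20me3 peaks, 39.3% met the full list of the other sex, where the lowest value among the other marks was 93.0%. Peak edges that narrowly miss each other are argued against, since 50.0% of peaks had a peak of the other sex within 5 kb, below the bound of 60% set in advance. Signal carried over from other marks could be tested only on the 928 of 9709 H4K20me3 peaks that met none of the other 5 marks. Of these, 22.2% met the other sex (33.2% of the female and 15.7% of the male ones), below the bound of 60% set in advance. Low sharing was thus also found away from the other marks. The test says nothing of the peaks that met another mark, so carry-over stays open for those. A difference between the sexes or strains and a difference between the immunoprecipitations or cultures remain open, as each sex had 1 list for the mark and no replicate values were analysed here.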
